A study of Arabidopsis thaliana with 12 samples.

How the data were processed

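Total RNA from roots of Arabidopsis thaliana, ecotype Wassilevskija, was profiled on an expression array. The titles name 6 wild-type (WT) samples and 6 samples of aap3, a mutant lacking the amino acid transporter AAP3, with replicate numbers 1 to 6 in each group. Nothing in the labels says whether replicates came from separate plants, pools or growth batches. The p-values therefore measure only the spread between these samples, which may be technical. The array type, the number of colours, the dyes, the scanner, the background correction and the normalization are not given in the sources used here.

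The deposited table holds 1 intensity per probe and sample on a linear scale, for 3439 probes with numbers up to 4607. The scale of these deposited intensities is unstated. Their lowest value is 0 and their highest lies just under 100, which at most 2 probes reached in any sample. Exact zeros made up 5.21% of all values. The 12 sample medians lay between 0.476 and 0.536, and between 158 and 199 probes per sample were at 0. The number of samples limits the precision, and no background reading was used here.

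The settings of the main comparison, the other settings to be tried and the rule for named genes were written before the data were examined. As planned for a share of zeros of 5% or more, each sample was divided by its median and values were floored at the 5th percentile of the positive values. This floor was 0.200 times the sample median, and 9.95% of values lay at or below it. Because log2 medians differed by up to 0.17 and interquartile ranges by up to 0.13, both over the planned limit of 0.1, the log2 values were quantile normalized. Fold changes of probes near the floor are understated by this step.

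The groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without covariates, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The plan asked for at least 3 values per group, and a floored value counts as a value, so all 3439 probes were fitted. Among them were 182 probes at the floor in all 12 samples, which have almost no spread and enter limma's shared variance estimate. Filters that leave out such probes had been run earlier and gave other counts, so this reading of the plan was settled after calls had been seen. The counts under 4 probe filters are given with the other alternatives.

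Same-numbered WT and aap3 samples deviated together from their group means, with correlations across probes of 0.73 to 0.75 in the 6 pairs. The numbers were therefore taken to pair the samples, from the data and not from a statement in the labels. A fit with the replicate number as a block is given beside the main count. On simulated values for 3439 probes, the fit without the block recovered 44% of probes changed by 0.4 and 83% of those changed by 0.8 on the log2 scale. With the block these shares were 74% and 97%. The simulated replicate numbers were independent of each other, no trend along probe numbers was included, and the dimmest 25% of probes were left unchanged. The shares may therefore be lower in the real data.

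Probe names came from GEO's platform annotation, updated through the TAIR10.1 gene table. A single gene was given for 692 probes, several genes for 870 and none for 1877. Of the single-gene probes, 690 matched a locus and 2 did not. No gene was named from a probe with several. No probe was paired with AAP3, so its level is not analysed here and the mutant labels were not checked by it. All 25 gene lists fixed beforehand had fewer than 5 measured members, so no list test was run on them, and no AAP family member was tested.

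The rule named the 10 probes with the smallest adjusted p in each direction. Because most of these carry no gene name, all 27 called single-gene probes are described as well, a choice made after their values were seen. Another 4 gene lists were also drawn up after the calls had been seen, and tested with camera at a preset correlation of 0.01, camera with an estimated correlation, and fry. Other settings fixed beforehand were median scaling, deposited values without scaling, an offset before log2, a filter on dim probes, fixed and random replicate blocks, a trended robust variance, sample weights, 1 probe per gene, and leaving out each sample. Settings chosen after seeing the data were subsets of replicates, averages of neighbouring replicate numbers, subtraction of the deviations of probes at nearby numbers, and the probe filters.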

Results

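Roots of the Arabidopsis aap3 mutant, which lacks the amino acid transporter AAP3, were compared with wild-type (WT) roots of the same ecotype, Wassilevskija. An expression array measured 3439 probes in 6 WT and 6 aap3 samples. The deposited intensities are linear on an unstated scale. Sample medians averaged 0.514 ± 0.018 in WT and 0.490 ± 0.011 in aap3 (SD, n = 6 each), and the aap3 sample had the lower median in all 6 replicate pairs. AAP3 itself and the other members of its family are not analysed here, since no single-gene probe was paired with them.

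The comparison asked which transcripts differ in roots without AAP3. Small differences in both directions were called with the 6 samples per group taken as independent. Averaging neighbouring replicate numbers left 1 call, as given below. Of 3439 probes, 172 passed an adjusted p of 0.05 in limma, 86 higher and 86 lower in aap3. Their median absolute change was 0.38 on the log2 scale, 14 exceeded 1.5-fold and 1 exceeded 2-fold, at 2.03-fold. Of the called probes, 171 went in a single direction in all 6 replicate pairs, as did 821 of all 3439 probes (23.9%). Probes without any difference would give 3.12% over 6 independent pairs and 25% over 3. The 25% assumes that neighbouring replicate pairs always go the same way, which their correlation of 0.54 to 0.65 does not ensure. The share of 23.9% over all probes therefore cannot tell whether the agreement exceeds what no difference would give. Single-gene probes made up 27 of the calls, 11 higher and 16 lower, out of 692 tested. With the replicate number as a block, 587 probes were called, 294 higher and 293 lower, of which 165 were shared with the 172. Values as deposited, without scaling between samples, gave 71 higher and 210 lower, with a median log2 difference over all probes of -0.05. The even split of the 172 therefore depends on the normalization between samples.

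**Figure D1:**
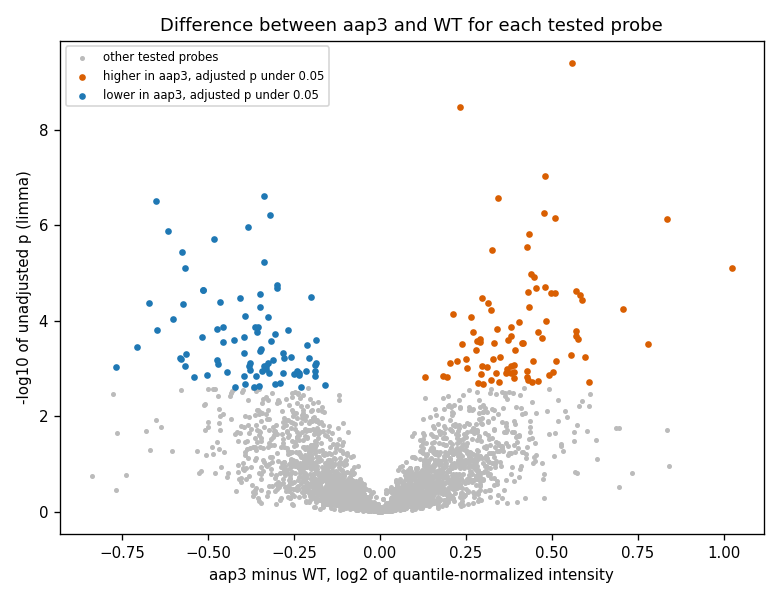
Difference between aap3 and WT (log2 of quantile-normalized intensity, horizontal) against the unadjusted p of limma (vertical, -log10) for each of 3439 probes, n = 6 per group. The 86 probes called higher in aap3 are orange, the 86 called lower are blue, and the largest change is 2.03-fold.

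Among named genes higher in aap3, AT1G62250 had the smallest adjusted p. Its deposited intensity averaged 4.80 ± 0.13 in WT and 6.87 ± 0.59 in aap3 (SD, n = 6), a log2 difference of 0.48 ± 0.04 (SE, limma adjusted p = 0.000104). Without the 182 probes at the floor in all samples, its limma adjusted p was 0.0016. The WD40-repeat gene AT3G09080 rose by 0.51 ± 0.07 (adjusted p = 0.0028), and AT5G33390 by 0.48 ± 0.08 (adjusted p = 0.00671). LpxA (AT4G29540), an acyltransferase of the lipid A type, rose by 0.48 ± 0.07, from an intensity of 1.44 ± 0.13 to 1.93 ± 0.13 (adjusted p = 0.00274). AT4G31470, of the family of PR-1-like secreted proteins, rose by 0.43 ± 0.07 (adjusted p = 0.00411). LrgB (AT1G32080), the plastid glycolate and glycerate transporter, rose 1.26-fold. The chloroplast chaperonin subunit Cpn60beta3 (AT5G56500) rose 1.23-fold, and CUTA (AT2G33740), a copper-binding chloroplast protein, 1.22-fold. On the log2 scale CUTA rose by 0.29, and by 0.44 with median scaling (limma adjusted p = 0.000134). AT4G27390 rose 1.24-fold, AT1G72640 1.27-fold and AT5G17280 1.19-fold. After the deviations of probes at nearby numbers were subtracted, the log2 difference was 0.09 for CUTA (limma adjusted p = 0.545), 0.07 for AT5G17280 (0.629), 0.17 for AT4G27390 (0.611) and 0.17 for AT4G31470 (0.107). LrgB, at 0.25 (0.103), and AT1G72640, at 0.24 (0.241), were not called either, though they moved by less than 1.5 times. With the replicate block added, LrgB (0.0118), AT1G72640 (0.014) and AT4G31470 (0.0254) stayed called. The subtraction overshot, as given below, so a call that ended after it is not shown to come from position.

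Among named genes lower in aap3, the changes in AT4G17070 and AT1G51350 were the largest. AT4G17070 fell by 0.77 ± 0.17 on the log2 scale, from an intensity of 22.3 ± 5.1 to 14.7 ± 4.2 (SD, n = 6; limma adjusted p = 0.0259). Its call ended with median scaling (-0.56, adjusted p = 0.191) and deposited values (-0.62, adjusted p = 0.144), and on leaving out WT replicate 1, 2, 3 or 4 or aap3 replicate 5 or 6 (adjusted p up to 0.0601). The armadillo-repeat gene AT1G51350 fell by 0.71 ± 0.14, from 2.03 ± 0.26 to 1.19 ± 0.24 (adjusted p = 0.0142). AT4G32060, the mitochondrial calcium uptake protein MICU, fell by 0.58 ± 0.07, from 5.22 ± 0.42 to 3.62 ± 0.40 (adjusted p = 0.000738). AT4G19900, a glycosyltransferase family member, fell by 0.48 ± 0.05 (adjusted p = 0.000476), and AT4G31530 by 0.46 ± 0.08 (adjusted p = 0.00816). With median scaling the difference was -0.46 for AT4G32060 and -0.36 for AT4G19900. That of AT4G31530 was -0.29 and its call ended (limma adjusted p = 0.0666). AT1G51350 (-0.72) and AT4G21170 (-0.33) were not smaller with median scaling, so sizes depend on the normalization in some genes and not in others. XERICO (AT2G04240), a RING-H2 protein tied to abscisic acid levels, fell by 0.37 ± 0.09 and lay just under the threshold (adjusted p = 0.0495, and 0.00293 with the replicate block). Its call ended with median scaling (adjusted p = 0.141) and in 10 of 12 omissions of 1 sample. AT5G05400, a disease resistance gene of the NB-LRR class, fell by 0.33 ± 0.05. AT4G29890, related to choline monooxygenase, fell by 0.32 ± 0.07, and AT1G62150, of the mTERF family, by 0.40 ± 0.08. The other 7 genes lower in aap3 were AT4G31060, AT4G19430, AT5G46560, AT4G21170, AT2G44760, AT3G04650 and AT3G52070, the last with the smallest change (fell by 0.19 ± 0.04). AT3G04650 was not called with the replicate block (adjusted p = 0.0751). XERICO, AT1G72640, AT2G44760, AT3G04650, AT3G52070 and AT5G17280 were not called when the 182 probes at the floor in all samples were left out of the fit, which gave 142 calls. After nearby deviations were subtracted, 15 of the 27 genes were not called, 5 with the replicate block. Among those lower in aap3, XERICO (-0.23), AT2G44760 (-0.15), AT4G29890 (-0.20) and AT4G19430 (-0.23) moved by over 1.5 times and AT1G62150 went to -0.27. The calls of AT4G31530 (-0.50 ± 0.16), AT5G05400 (-0.35 ± 0.12), AT5G46560 (-0.33 ± 0.09) and AT3G52070 (-0.19 ± 0.07) ended at about the size they had before, with a larger SE, and held with the replicate block.

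**Figure D2:**
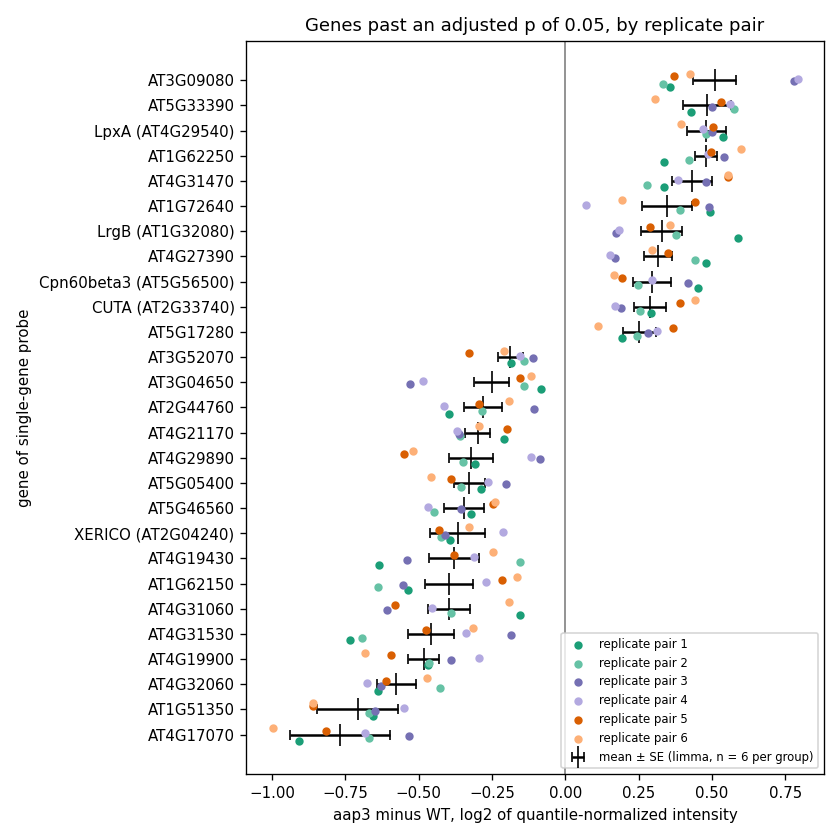
Difference between aap3 and WT (log2 of quantile-normalized intensity, horizontal) for the 27 called single-gene probes (vertical). Points are the 6 replicate pairs and bars the mean ± SE of limma, from -0.77 for AT4G17070 to 0.51 for AT3G09080. All 27 genes went in a single direction in all 6 pairs, as did 171 of all 172 called probes.

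Most of the strongest calls carry no gene name. Of the 10 probes with the smallest adjusted p among those higher in aap3, 9 are unnamed and 1 is AT1G62250. Several lie close together by number: 2909, 2917, 2921 and 2923, near LpxA at 2903, and 3493 and 3499. Probe 3499 (limma adjusted p = 5.76e-06) reached the highest deposited value in 5 aap3 samples and in 0 WT samples. Its deposited WT intensities averaged 81.2 ± 10.2 (SD, n = 6). Quantile normalization removed this spread, as leaving out any WT sample left the log2 difference at 0.23. With median scaling the limma adjusted p of probe 3499 was 0.0441, and with deposited values 0.046. The very small adjusted p of probe 3499 therefore depends on the normalization. Probe 2917 had the smallest adjusted p of all in the main fit, with a log2 difference of 0.56 ± 0.03 (SE, limma adjusted p = 1.39e-06). Without the 182 probes at the floor in all samples, the limma adjusted p was 0.00048 for probe 2917 and 0.0187 for probe 3499. Both calls held, but the size of these main adjusted p-values depends on the probes at the floor. After nearby deviations were subtracted, probe 2917 had a difference of 0.26 (adjusted p = 0.0268). Probe 3499 went from 0.23 to 0.03 and its call ended (limma adjusted p = 0.91). The calls of probes 2921 (0.371) and 3493 (0.0578) ended too, and the others of these 10 stayed called. Of the 10 among those lower in aap3, 4 are unnamed, 3 match several genes and 3 are AT4G19900, AT4G32060 and AT4G21170. Probe 3656 fell by 0.65 ± 0.06 (adjusted p = 0.000177).

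The gene lists fixed beforehand could not be tested at this coverage. Their 1 measured member, GLR2.7 (AT2G29120), a glutamate receptor-like channel, had a log2 difference of -0.28 ± 0.23 (limma adjusted p = 0.637). AT2G28390, often used as a reference gene, had a difference of 0.14 ± 0.10 (adjusted p = 0.526). In a list of 18 genes of plastid biogenesis and pigments, drawn up after the calls had been seen, Cpn60beta3 rose and 17 were not called; with the replicate block 5 were called, 2 higher and 3 lower. The list did not pass camera (adjusted p = 0.602, and adjusted p = 0.763 with an estimated correlation). In fry it did not pass for movement one way (adjusted p = 0.468), and its test for change in either direction, which compares with no other genes, gave an adjusted p of 0.0332 on a list chosen with the call of Cpn60beta3 in view. Camera also passed none of 10 genes of photosynthesis, 5 of cell wall enzymes and 5 of floral regulators, which held no call (adjusted p = 0.602, 0.602 and 0.891, and 0.763, 0.763 and 0.892 with an estimated correlation), and fry passed none of them in one direction (adjusted p = 0.569, 0.347 and 0.86) or in either (adjusted p = 0.121, 0.382 and 0.757). With the replicate block 1, 1 and 2 of their members were called.

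The 6 replicate pairs did not behave as 6 equally distant repeats. Differences between aap3 and WT correlated across probes at 0.54 to 0.65 between replicates 1 and 2, 3 and 4, and 5 and 6, and at 0.32 to 0.35 between all other pairs. With each of these couples averaged to 1 value per group, limma called 1 probe (373 at an unadjusted p under 0.05), and 0 with the replicate block (755). Both unadjusted counts lie above a 0.05 share of the 3439 probes, though probes are not independent of each other. With 3 values per group, the lost calls do not show that the differences are absent. No named gene was called in either of these fits. Pair differences with the couples as a random block, which estimates how alike they are, gave 280 calls, 42 of them single-gene, and kept 36 of the 43 probes named by rule or by gene. If the couples are repeat measurements, the p-values over 6 samples per group are too small.

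**Figure D3:**
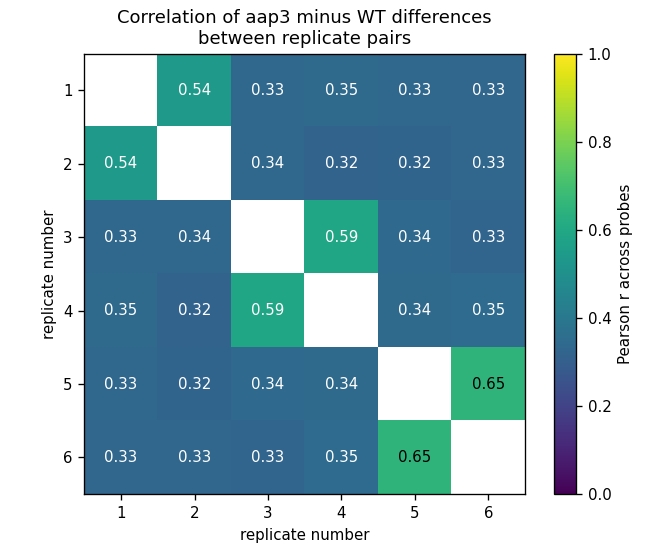
Pearson correlation across 3439 probes of the aap3 minus WT differences (log2) between replicate pairs 1 to 6 (both axes). The 3 couples of neighbouring numbers lie at 0.54 to 0.65 and all others at 0.32 to 0.35.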

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

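The tests of array position and dyes and the exchanges by couples were chosen after the calls were seen. Among 90 checks for a sample far from its group, 2 stood out, fewer than the 1 in 20 that chance gives. On the quantile-normalized log2 scale, AT1G62250 was lower in WT replicate 6, at 3.19 against 3.29 to 3.35 in the other WT samples, a gap of 0.644 of the range. The unnamed probe 3199 was higher in WT replicate 2, at -0.06 against -0.34 to -0.24 on that scale, a gap of 0.671 of the range. In the deposited intensities, which were not tested this way, these samples stood at 4.58 against 4.76 to 4.99 and at 0.494 against 0.392 to 0.452, so the gaps are a smaller part of the range there.

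The calls between aap3 and WT were weighed against chance, array position and dyes. Of 100 splits of the 12 samples, 1 gave as many calls, the real one with 172, and the highest other gave 92, with replicates 5 and 6 on one side. Of 32 exchanges of labels within pairs, 1 gave as many calls with the replicate block, the real one with 587, and the highest other gave 0. Chance is excluded only if the 6 pairs are independent: with the couples 1 and 2, 3 and 4, 5 and 6 exchanged together there are 4 exchanges, of which 1, the real one, gave as many (highest other 0), too few for a share under 0.05. Swapped dyes are argued against by the lowest correlation of pair differences, 0.32, but dyes in a constant orientation cannot be told apart from genotype, since both give the single direction seen in 171 of 172 calls. After the deviations of probes at nearby numbers were subtracted, 440 of the 587 probes called with the block stayed called, among them 137 of the 165 called both with and without it, which argues against the trend removed as the whole cause; without the block 89 of the 172 stayed called, which does not decide. The subtraction overshot, as the correlation of differences between probes 6 numbers apart went from 0.18 to -0.15. Between probes 1 number apart it went from 0.09 to -0.21, further below 0 than it had been above. A call that ended after the subtraction is therefore not shown to come from position. A contribution of position stays open beside an effect of the mutation.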

How the results depend on the processing

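Subsets and averages of replicates, nearby-probe subtraction and the probe filters were chosen after seeing the data. No named probe changed direction under any alternative. The count of 172 calls (27 single-gene) moved by less than 1.5 times under median scaling (182, of which 157 shared), an offset (181, 170 shared), the dim filter (163, 142 shared), a trended robust variance (170, all shared), sample weights (208, 167 shared) and 1 probe per gene (172, all shared). Nearby subtraction gave 178, of which 89 shared, and kept 12 of the 27 genes. Leaving out each sample gave 128 to 188 calls, 66 to 86 higher, 58 to 102 lower and 19 to 32 single-gene. Of the 27 genes, 17 kept their call in all 12 omissions. Omissions ended the calls of Cpn60beta3 (3 omissions), AT4G17070 (6), AT5G17280 (6), AT3G52070 (7), AT4G29890 (7), AT2G44760 (7), AT4G19430 (8), AT3G04650 (8), AT1G72640 (9) and XERICO (10), with adjusted p up to 0.0943. Median scaling ended those of AT4G17070, AT4G31530, AT1G72640 and XERICO. Of 4 probe filters, the first 2 were run before the reading of the plan was settled: they gave 142 calls without the 182 probes at the floor throughout (74 higher, 68 lower, 21 single-gene), and 181 without probes at 0 throughout; asking for 3 positive values per group gave 178. Probes above the floor in all samples gave 157. The replicate block gave 587 (294 higher, 293 lower, 101 single-gene), and as a random block 713 (358, 355 and 118); of named genes the fixed block changed only the call of AT3G04650. Values as deposited gave 281 (71 higher, 210 lower, 47 single-gene), with aap3 medians unscaled. Nearby subtraction with the replicate block gave 817 (397, 420 and 147). Replicates 5 and 6 alone, with the block, gave 0 in each direction and 0 single-gene (1016 at an unadjusted p under 0.05), with only 2 pairs, and replicates 1 to 4 gave 248. Couples averaged gave 1 call (1 higher, 0 lower, 0 single-gene), and 0, 0 and 0 with the replicate block, with 3 values per group. Of 43 named probes, these averages ended 42 calls without and 43 with the block, and nearby subtraction ended 18 without and 7 with the block. Pair differences with couples as a random block gave 280 (160 higher, 120 lower, 42 single-gene). Where no construction is named, the cause was not tested. AAP3, its family and the planned gene lists gave no value under any setting. Signal over background was not used here.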

Other observations

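The tests of couples and of chromosome 4 were chosen after the patterns were seen in the correlations and the calls. With the replicate block, limma called 75 single-gene probes that the fit without it did not, and the genes below were picked from these after their values were seen. Histone H3 genes AT1G09200 and AT1G13370 were higher in aap3, by 0.63 ± 0.11 and 0.31 ± 0.04 on the log2 scale (SE with the block, adjusted p = 0.0174 and 0.0107), in 6 of 6 pairs. A probe for another histone H3 gene, AT5G65360, lay at the floor in all 12 samples and gave no measurable level. Neither of the 2 was called without the block (adjusted p = 0.214 and 0.1), and as their sequences are close, a probe that reads both was not excluded. LHB1B2, a light-harvesting protein, was higher by 0.63 (block adjusted p = 0.0441), GH9B8, an endoglucanase, by 0.44 (0.018) and SIRB, a chelatase of siroheme synthesis, by 0.35 (0.0198). HEMA3, a glutamyl-tRNA reductase, fell by 0.23 (0.0156), GLDH, of ascorbate synthesis, by 0.28 (0.0441), and the proteasome subunit AT5G23540 by 0.47 (0.0122). Each went in a single direction in 6 of 6 pairs, as did 569 of the 587 probes called with the block. That agreement follows largely from the call and adds no support to it.

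Replicate numbers went in couples. A candidate explanation is repeated measurement of the same material: the lowest correlation of pair differences within couples was 0.54 and the highest across them 0.35. Only 1 of the 15 ways of coupling 6 replicates was as high, which is the smallest share the design allows and lies above 0.05. A shared growth batch or day would give the same correlations and cannot be told apart from repeated measurement, since the labels name neither. After nearby deviations were subtracted, the lowest within was 0.46 and the highest across 0.41, which leaves array position open as well. No biological explanation was tested.

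Called genes were frequent on chromosome 4, with 11 of 120 measured genes against 16 of 570 elsewhere (Fisher's exact test, two-sided, adjusted p = 0.0152 over 5 chromosomes). With the replicate block it was 23 of 120 against 78 of 570 (adjusted p = 0.771), with median scaling 9 of 120 (adjusted p = 0.181) and after nearby subtraction 7 of 120 (adjusted p = 0.563), so the pattern depends on the setting, with and without the block, and chance cannot be excluded. The 11 genes ran from AT4G17070 to AT4G32060, a span of 55 measured genes, as short in a share of 0.002 of 10000 random draws, but with the block the share was 0.758. A linked segment carried by the mutant line may be a hypothesis for this, and AAP3 itself lies on chromosome 1 by its locus tag. Position on the array stays open too, with 6 of the 11 called after nearby subtraction.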
